A study of Mus musculus with 2 samples.

How the data were processed

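RNA-seq of RNA described as polyadenylated was deposited for 2 libraries of G1E-ER4 mouse cells, and for each library a gene table and a transcript table were used. Expected counts and posterior mean counts in these tables are estimated counts that need not be whole, per the file headers. TPM and posterior mean TPM are the authors' transcript abundances scaled to a fixed total, per the file headers, and FPKM was likewise deposited by the authors. The isoform share is a percent of the gene's TPM, as deposited by the authors. Bounds of an interval on TPM are also in the files and were not used here, since their level is not given in the sources used here. The build is mm10 and the annotation GENCODE M4, per the labels and the readme files. The aligner and the quantifier are not given in the sources used here, nor is whether counting used strand, so genes that overlap on opposite strands are uncertain. The labels give a fragment size above 175, with no unit.

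Each gene table held 69691 features, of which 43346 were Ensembl genes, 97 spike-ins and 26248 rows with numeric identifiers. Spike-ins had 0 counts in both libraries, and the numeric rows had 0 and 1 count. Gene names, classes and coordinates came from GENCODE M21, which uses the same build, by identifier without version, and 42462 genes matched. Genes without a name held 0.283% of counts in Ensembl genes. Transcript models of M4 and M21 can differ, so GC content and class refer to M21. Of the 271 symbols in the gene lists 3 found no match and are not reported.

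Samples were grouped by their labels into 1 group of 2 replicates, with 68901065 and 51923117 estimated counts. No test between conditions exists in this design. Levels are means and SDs of TPM over both libraries, and a gene was called detected at 1 TPM or more in both. For each of 25 gene lists, fixed before the data were examined, the median of the mean TPM was set against 10000 seeded random lists of the same size from protein-coding genes. As an alternative the random lists came from protein-coding genes at 1 TPM or more in both libraries, while each gene list kept all its members. The lists covered erythroid transcription factors, haem synthesis, globins, red cell membrane, iron handling, red cell enzymes and redox, late erythroid maturation, progenitor genes, cytokine signalling, estrogen receptors and targets, S phase, G2 and M phase, CDK inhibitors, the BCL2 family, stress genes, housekeeping genes and non-coding RNA, and 8 other cell types. Those were megakaryocyte, mast cell and basophil, granulocyte and macrophage, T cell, B cell, endothelial, fibroblast and pluripotent stem cell.

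Named genes followed a rule fixed before the data were examined. Gata1 came first, then the 4 highest members of each list, every globin, every erythroid transcription factor and progenitor gene, and members of other cell type lists at 1 TPM or more in both libraries, the 4 highest where more. The 20 most abundant genes, the 5 genes most above and 5 most below between the libraries, and a fixed set of 12 genes for isoforms followed, with the 5 most abundant genes whose leading transcript differed. Low members of the lists, such as Slc4a1, Epb42, Uros, Tfrc, Tbp and Bcl2, were named after their values were seen, as were ratios between genes and members of lists that differed between the libraries. Some genes that the rule names are not reported here.

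Expected counts were rounded to whole numbers for tests. Library scaling by TMM and the biological coefficient of variation came from edgeR 4.0.16 in R 4.3.3 with an intercept-only design on genes with a mean of at least 10 counts. Differences between the libraries were tested per gene by an exact two-sided binomial test in scipy 1.17.1, with the expected share from the scaled library sizes and Benjamini-Hochberg adjustment at 0.05. Zero counts entered ratios at a floor of 3 counts per library. Shares of counts have 95% Clopper-Pearson intervals, and intervals and floors cover counting error only, since reads from PCR are not independent molecules. At this depth the interval of the globin share is far narrower than the spread between the libraries, so the spread and not depth limits abundant genes.

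The binomial test was tested on simulated counts for the 10863 genes of the comparison of replicate 2 with replicate 1, with 50 genes changed at each fold. These counts held counting error alone, which is what the test assumes. The check therefore cannot show how the test behaves under the larger spread of the real libraries. It called 90.0% of genes raised 2-fold, 86.0% of those lowered to 0.5, 100% of those raised 4-fold and 96.0% of those lowered to 0.25, and 0.0844% of the 10663 unchanged genes. A simulated coefficient of variation of 0.1 was recovered as 0.101 and one of 0.3 as 0.298.

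Alternatives were other TPM minimums, FPKM, CPM, posterior mean values, TPM without globin and mitochondrial genes, other pseudocounts and count filters, DESeq2 1.42.0 size factors, library totals, an exact negative binomial test with a coefficient of variation of 0.1, and each library alone. Folds between the libraries from TPM were added after the data were seen. GC content, length and 31-mers of a gene refer to its longest protein-coding transcript, or to its longest transcript where none is coding. GC content was known for 99.7% of genes with a mean of at least 10 counts. The percent of 31-mers shared with another gene was computed from the M21 transcripts.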

Results

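RNA described as polyadenylated was measured by paired-end RNA-seq in G1E-ER4 cells, an immortalized mouse erythroid line. The parent G1E cells lack Gata1, and G1E-ER4 cells carry a GATA1 protein fused to the ligand-binding domain of an estrogen receptor, so that estradiol switches its activity on. The labels describe cells with Gata1 restored and differentiation induced by estradiol, with neither dose nor duration. The 2 libraries form 1 group and are labelled biological replicates 1 and 2. Both cite the same biosample record, so their spread may be technical. P-values between the libraries hold counting error alone and do not measure the spread between samples. The gene tables held 68901065 estimated counts in replicate 1 and 51923117 in replicate 2. With 1 group no condition could be compared, and the question addressed is which erythroid, progenitor and other genes these cells, labelled as induced, expressed, and how closely the libraries matched.

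Gata1, the transcription factor restored in this line, stood at 1498 TPM in replicate 1 and 2430 TPM in replicate 2, a mean of 1964 ± 659 TPM (SD, n = 2). The gene (ENSMUSG00000031162) is protein-coding and lies on the minus strand of chromosome X, from 7959260 to 7978071 in mm10. Reads of the fusion transgene and of the endogenous locus are not separated in these values. All 13 erythroid transcription factors reached 1 TPM in both libraries, with a median of 253.7 TPM. This median lay above every one of 10000 random lists of 13 protein-coding genes and above every one drawn from protein-coding genes at 1 TPM or more in both libraries, here called expressed genes. Most protein-coding genes are not expressed here, so a high percentile among lists of all of them shows little more than expression, and the percentile among lists of expressed genes stands beside it for each list with a median of 1 TPM or more. Gene lists kept their undetected members in that comparison, which lowers the percentile. A low value there therefore does not show that the detected members of a list are low. The LMO2 complex partners were abundant, with Ldb1 at 725 ± 106 TPM, Lmo2 at 687 ± 142 TPM and Tal1 at 239 ± 37.6 TPM (SD, n = 2). Zfpm1, which encodes the GATA1 cofactor FOG1, stood at 690 ± 33.3 TPM, Gfi1b at 447 ± 74.3 TPM and the erythroid activator Klf1 at 428 ± 72.9 TPM (SD, n = 2). Cbfa2t3 had 254 TPM, Nfe2 157, Zbtb7a 117, the fetal globin repressor Bcl11a 115, Foxo3 83.8 and the cell cycle regulator E2f2 46.8 TPM, as means of the 2 libraries.

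Genes of earlier progenitors were also present, 10 of 14 at 1 TPM or more in both libraries, with a median of 40.5 TPM at percentile 99.97 of random lists and 89.2 of lists of expressed genes. Gata2, the GATA factor of stem and progenitor cells (chromosome 6, 88193891 to 88207032), stood at 963 ± 93.6 TPM (SD, n = 2). It was 2.15 times the level of Klf1 in replicate 1 and 2.38 times in replicate 2. Gata1 in turn stood 1.46 and 2.71 times above Gata2, a ratio that moved more between the libraries. The proto-oncogene Myc had 763 ± 109 TPM, Lyl1 446 ± 5.92 TPM, Hhex 384 ± 69.3 TPM and Runx1 220 ± 12.2 TPM (SD, n = 2). The stem cell factor receptor gene Kit had 54.4 TPM, the myeloid and B-lymphoid factor Spi1 42.4, Myb 38.6, Fli1 8.66 and Meis1 3.98 TPM as means of the 2 libraries. Erg at 0.82 TPM, Gfi1 at 0.32 and 0.03 TPM in the 2 libraries and Cd34 at 0.03 TPM stayed below 1 TPM on average, and Hoxa9 had no count in either library. A count of 0 allows up to 3 counts, which is 4.35e-06% of the total in replicate 1 and 5.78e-06% in replicate 2, for counting error only.

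**Figure D1:**
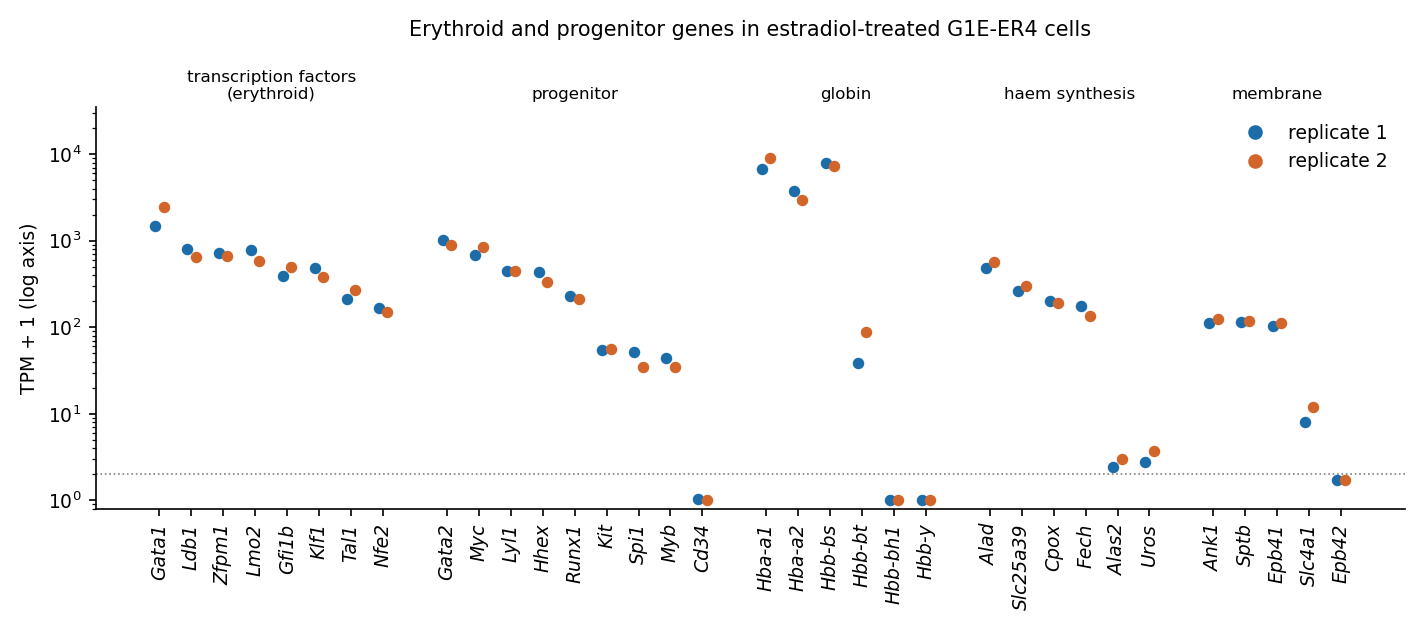
TPM + 1 on a log axis for erythroid transcription factors, progenitor genes, globins, haem synthesis genes and red cell membrane genes, with a point for each library and a dotted line at 1 TPM. Gata2 lies near 963 TPM, whereas Alas2 at 1.72 TPM and Epb42 at 0.72 TPM lie near the line.

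Adult globin transcripts made up 1.88 ± 0.0459% of TPM (SD, n = 2), and embryonic globins were not detected. In counts the globin share was 0.604% in replicate 1 (95% Clopper-Pearson interval 0.602 to 0.606%) and 0.629% in replicate 2 (0.627 to 0.631%), whereas TPM divides by transcript length. Hba-a1 (chromosome 11, 32283511 to 32284465) stood at 7841 ± 1548 TPM, Hba-a2 at 3358 ± 625 TPM and Hbb-bs (chromosome 7, 103826534 to 103828096) at 7588 ± 499 TPM (SD, n = 2). The alpha genes are near-identical, so their split is uncertain and their sum, 11199 ± 924 TPM, is the firmer value. Alpha over beta globin was 1.32 in replicate 1 and 1.62 in replicate 2. The beta copy Hbb-bt had 37.9 and 86.2 TPM. It shares 59.4% of its 31-mers with another gene and Hbb-bs shares 66.9%, so the beta split is uncertain too, and the beta sum was 7650 ± 464 TPM (SD, n = 2). Hba-x, Hbb-y and Hbb-bh1, the embryonic genes, had 0 counts in both libraries, as had Hbq1a, Hbb-bh0 and Hbb-bh2, and Hbq1b stood at 0.12 and 0.43 TPM. Of the 11 globin genes 4 were detected, and the list median of 0 TPM, set by the 6 members with no count, lay at percentile 15.96 of random lists and says nothing of the level of the others.

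Genes of haem synthesis and its transport steps were all at 1 TPM or more, 14 of 14, with a median of 64.6 TPM above every random list and at percentile 97.9 of lists of expressed genes. Alad, the enzyme that condenses aminolevulinic acid, stood at 524 ± 60.03 TPM, the mitochondrial carrier Slc25a39 at 283 ± 26.7 TPM, Cpox at 193 ± 7.29 TPM and Tmem14c at 170 ± 52.0 TPM (SD, n = 2). Alas2, the erythroid enzyme of the first step of the pathway (chromosome X, 150547375 to 150570638), stood at 1.44 and 2.0 TPM, from 75 and 119 counts. Alad was 335 times above it in replicate 1 and 283 times in replicate 2, beyond the spread between the libraries. The uroporphyrinogen III synthase gene Uros was similarly low at 2.24 TPM.

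Red cell membrane genes were uneven, with 15 of 17 at 1 TPM or more in both libraries and a median of 9.01 TPM. That median lay at percentile 97.9 of random lists but at 4.495 of lists of expressed genes. The cytoskeletal genes Ank1 at 117 ± 9.24 TPM, Sptb at 116 ± 2.22 TPM and Epb41 at 108 ± 5.48 TPM (SD, n = 2) and the surface protein gene Ermap at 98.8 ± 15.4 TPM led the list. The anion exchanger gene Slc4a1 had 9.01 ± 2.74 TPM and Epb42 0.72 ± 0.0283 TPM (SD, n = 2). Kit exceeded Slc4a1 7.58 times in replicate 1 and 5.05 times in replicate 2. Aqp1 had no count. Among late erythroid maturation genes 8 of 11 were detected, with a median of 5.68 TPM at percentile 91.5 of random lists but 1.78 of lists of expressed genes. The autophagy genes Ulk1 at 51.9 TPM, Gabarapl1 at 50.4 TPM and Map1lc3b at 38.3 TPM and the mitophagy receptor gene Bnip3l at 36.3 TPM were the highest, whereas Trim58 and Alox15 each had 1 count in 1 library.

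Iron handling was led by the ferritin chains, with Fth1 at 17424 ± 3216 TPM and Ftl1 at 12465 ± 629 TPM (SD, n = 2). The iron chaperone gene Pcbp1 had 1493 TPM and the ferrireductase gene Steap3 122.0 TPM, whereas the transferrin receptor gene Tfrc had 18.4 TPM in replicate 1 and 6.93 TPM in replicate 2. Of 13 members 12 were detected, and the median of 12.7 TPM lay at percentile 98.0 of random lists but 19.5 of lists of expressed genes. Red cell enzymes and redox genes were detected in full, 13 of 13, with a median of 303 TPM above every random list of either kind. Blvrb, a biliverdin reductase gene, stood at 1028 ± 76.8 TPM, Sod1 at 624 ± 157 TPM and Gclm at 612 ± 101 TPM (SD, n = 2), and the carbonic anhydrase gene Car2 had 337 TPM in replicate 1 and 1000.1 TPM in replicate 2, a mean of 669 TPM.

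**Figure D2:**
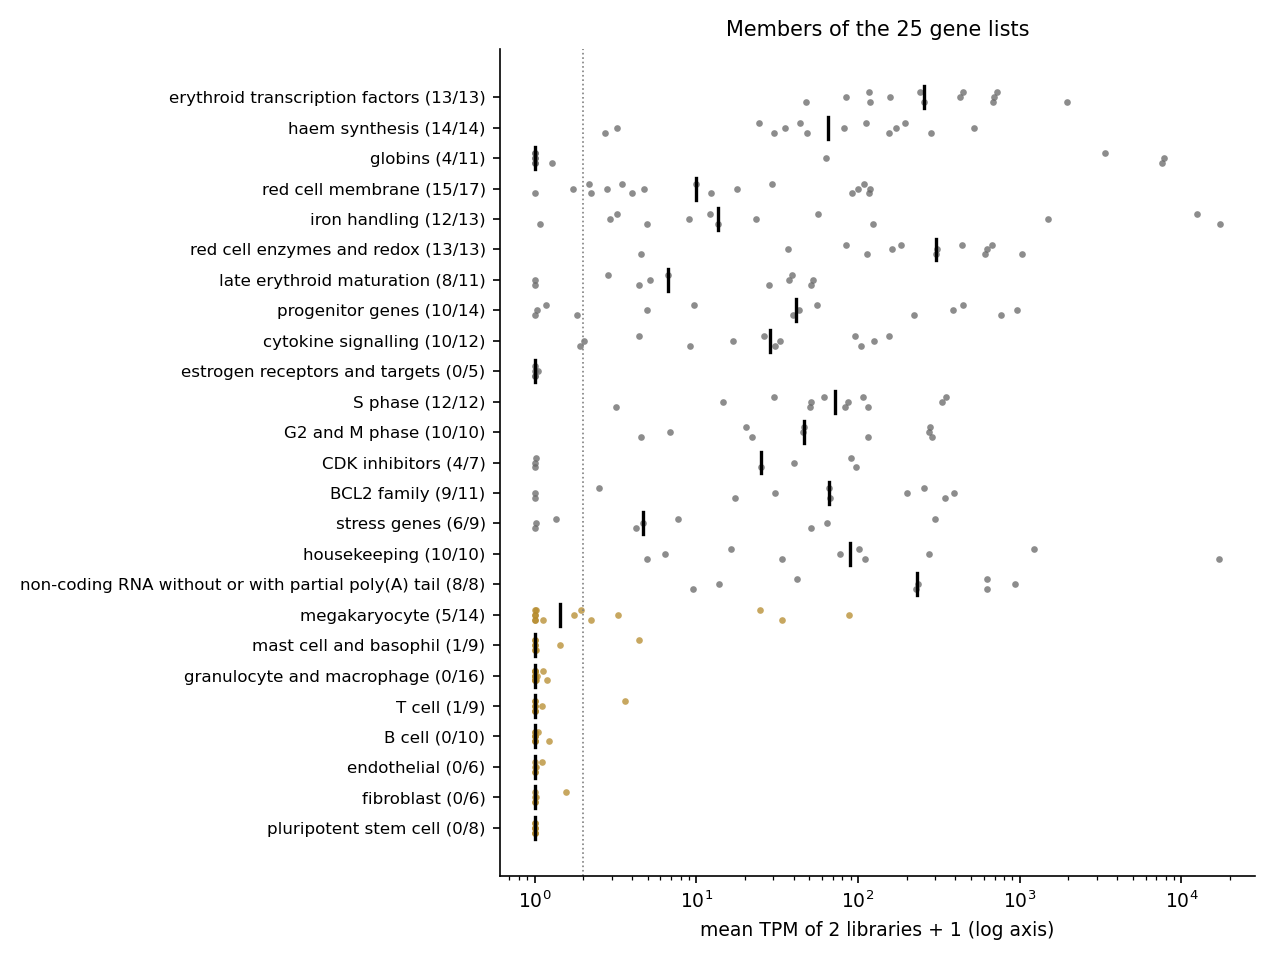
Mean TPM + 1 of the 2 libraries on a log axis for each member of the 25 gene lists, with the list median as a black bar, a dotted line at 1 TPM, and the number of members detected in both libraries over the number measured beside each name. Lists of erythroid and general genes are grey and lists of other cell types are ochre, and 7 of 78 members of the latter were detected.

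The erythropoietin receptor gene Epor led cytokine signalling at 154 ± 30.3 TPM, followed by the STAT5 target genes Cish at 125 ± 4.46 TPM, Pim1 at 103 ± 10.3 TPM and Socs2 at 95.2 ± 11.2 TPM (SD, n = 2). That list had 10 of 12 members detected and a median of 27.5 TPM at percentile 99.7 of random lists and 68.4 of lists of expressed genes. None of the 5 estrogen receptors and targets was detected. Esr1 stood at 0.045 TPM from 2 counts in each library, Esr2, Greb1, Pgr and Tff1 had no count, and the median of 0 TPM lay at percentile 18.6 of random lists. Reads of the receptor part of the fusion need not be counted at Esr1, so these values do not show whether it was expressed. Genes of the cell cycle were expressed throughout, with all 12 S phase genes and all 10 genes of G2 and M phase detected. S phase genes had a median of 71.5 TPM, above every random list and at percentile 98.4 of lists of expressed genes, led by Rrm2 at 348 TPM, Mcm2 at 331, Mcm5 at 115 and Mcm4 at 106 TPM. G2 and M phase genes had a median of 45.1 TPM, at percentile 99.8 of random lists and 88.0 of lists of expressed genes, led by Aurkb at 287 TPM, Ccna2 at 278, Cdc20 at 272 and Plk1 at 115 TPM. CDK inhibitors were present beside them, 4 of 7 with a median of 24.1 TPM at percentile 97.5 of random lists and 57.7 of lists of expressed genes, namely Cdkn2c at 95.7 TPM, Cdkn1a at 89.8, Cdkn1b at 39.3 and Cdkn2d at 24.1 TPM.

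In the BCL2 family 9 of 11 members were detected, with a median of 65.4 TPM at percentile 99.96 of random lists and 97.0 of lists of expressed genes. The survival gene Mcl1 had 394 TPM, and the pro-apoptotic genes Bax, Bbc3 and Bak1 had 345, 255.4 and 201 TPM. Bcl2l1, the survival gene of maturing erythroid cells, stood at 65.9 ± 17.6 TPM (SD, n = 2), 37.6 and 49.9 times above Bcl2 in the 2 libraries. Stress genes were mostly low, 6 of 9 detected with a median of 3.71 TPM at percentile 85.6 of random lists but 0.425 of lists of expressed genes. They were led by Hsp90aa1 at 296 TPM, a mean of 405 TPM in replicate 1 and 187 TPM in replicate 2, Ddit3 at 63.1, Egr1 at 50.1 and Hmox1 at 6.71 TPM. All 10 housekeeping genes were detected, with a median of 88.2 TPM at percentile 99.99 of random lists and 98.8 of lists of expressed genes. They ranged from Gapdh at 17157 TPM and Actb at 736 TPM in replicate 1 and 1696 TPM in replicate 2, through Ywhaz at 273 TPM and Ppia at 110 TPM, down to Tbp at 3.95 TPM. The 8 non-coding RNAs without or with partial poly(A) tail were all present, with a median of 231 TPM above every random list of protein-coding genes and at percentile 99.97 of lists of expressed ones. They stood at these levels although the RNA is described as polyadenylated, and the cause was not tested. TPM divides by length, and the short Rmrp stood at 160 and 308 TPM from only 1079 and 1716 counts. Malat1 was the lowest of the 8 at 8.26 and 8.95 TPM. Rn7sk stood at 936 ± 0.0566 TPM, Rmrp at 234 ± 105 TPM (SD, n = 2), and Rn7s1 and Rn7s2 were listed at the same 627 TPM, as near-identical copies that can share reads.

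Few markers of other cell types were detected, 7 of 78 members at 1 TPM or more in both libraries. The percentiles given are those of random lists of all protein-coding genes. The megakaryocyte list held 5 of them, of 14 members, with a median of 0.448 TPM at percentile 66.1. Nbeal2 stood at 86.6 ± 5.23 TPM, Gp1ba at 32.9 ± 2.75 TPM, Itga2b at 23.7 ± 7.90 TPM and Treml1 at 2.31 ± 0.629 TPM (SD, n = 2), whereas Gp6, Ppbp and Selp had no count. Of 9 mast cell and basophil genes 1 was detected, Hdc at 3.42 TPM, with the list median of 0.005 TPM at percentile 36.4. Of 9 T cell genes 1 was detected, Lck at 2.63 TPM, with a median of 0.005 TPM at percentile 36.1. In replicate 2 or replicate 1 alone the percentile was 20.8 or 19.4 for the mast cell and basophil list and 20.7 or 18.99 for the T cell list. The lists of granulocyte and macrophage (0 of 16, percentile 10.04), B cell (0 of 10, percentile 10.7), endothelial (0 of 6, percentile 11.0), fibroblast (0 of 6, percentile 31.5) and pluripotent stem cell genes (0 of 8, percentile 11.1) had none. All 8 pluripotency genes, among them Pou5f1 and Nanog, had 0 counts in both libraries.

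Genes at 1 TPM or more numbered 9115 in replicate 1, 9135 in replicate 2 and 8884 in both. Of the latter 8376 were protein-coding, 39.0% of the 21474 protein-coding genes in the tables. The 20 most abundant genes took 23.2% of TPM in replicate 1 and 23.3% in replicate 2. Ribosomal protein genes filled 10 of these places, led by Rplp1 at 26786 ± 890 TPM and Rpl18 at 19825 ± 3182 TPM (SD, n = 2), with Rpl28, Rpl41, Rpl27a, Rpl36, Rps15, Rpl13a, Rps14 and Rps26 between 5392 and 12629 TPM on average, Rps26 at 2008 TPM in replicate 1 and 8775 TPM in replicate 2. Fth1, Gapdh and Ftl1 were among the 8 highest, beside the histone gene Hist1h2ap at 15020 ± 6639 TPM and the prothymosin gene Ptma at 14160 ± 3364 TPM (SD, n = 2). Gm42418 at 9933 ± 282 TPM and Gm26917 at 8142 ± 686 TPM (SD, n = 2) lie side by side on chromosome 17, from 39843013 to 39848788, where RefSeq places an 18S ribosomal RNA related sequence. Hba-a1, Hbb-bs and the metallothionein gene Mt2 at 5771 ± 2058 TPM completed the list. Median TPM of protein-coding genes with a mean of at least 10 counts rose with GC content, from 3.51 and 3.15 TPM in the lowest decile to 38.9 and 35.2 TPM in the highest, so levels of genes of unlike GC content are compared here with that limit.

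The libraries ranked genes alike. Across 10863 genes with a mean of at least 10 counts, log2(TPM + 1) had a Pearson correlation of 0.974 and a Spearman correlation of 0.972, computed across genes, which are not independent replicates. The log2 ratio of replicate 2 to replicate 1 in scaled counts had a median of -0.01 and an SD of 0.72. TMM scaling places that median near 0, so only the SD describes how closely the libraries matched. The common biological coefficient of variation was 0.2995. An exact two-sided binomial test, which compares these libraries and not conditions and holds counting error alone, called 7502 genes (69.1%) at a Benjamini-Hochberg adjusted p of 0.05. Of these, 3769 were higher in replicate 2 and 3733 in replicate 1, and with library totals as the scaling 3065 and 4756 were. Among genes called and at least 2-fold apart, 810 were higher in replicate 2 and 182 in replicate 1. That split was 680 to 252 with library totals, 602 to 44 at a mean of at least 100 counts and 798 to 240 with folds from TPM. At this depth counting error is small in abundant genes, most calls were of less than 2-fold, and with a coefficient of variation of 0.1 added, below the 0.2995 estimated, 2046 genes were called.

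Several of the largest ratios between the libraries belonged to pseudogenes or to genes that share sequence. Of 840 genes over 2-fold higher in replicate 2 on the ratio of scaled counts, 198 shared at least 50% of 31-mers and 241 shared none. These were 17.6% of the 1123 tested genes sharing at least 50% and 6.67% of the 3615 sharing none. Such differences were thus more frequent in genes that share sequence but were not confined to them. Among genes with a mean of at least 100 counts, the processed pseudogenes Gm10231, Gm11518 and Gm12481 and the unnamed genes ENSMUSG00000103212 and ENSMUSG00000103319 had 0 counts in replicate 1 and stood at least 1295, 237, 231, 142 and 123 times higher in replicate 2, against a floor of 3 counts. In replicate 1, Pet117, Trim17, mt-Co2 and Tgif2-ps2 stood at least 215, 161, 77.5 and 73.7 times higher against the same floor, and Ywhaq-ps3 stood 15.5 times higher. All 31-mers of Pet117, mt-Co2 and the 3 named processed pseudogenes occur in another gene, so their counts are uncertain. Trim17 shares 22.5% of its 31-mers, and the unnamed genes have no such value. Tested members were 13 erythroid transcription factors, 11 progenitor genes and 12 cytokine signalling genes. None of these was called and at least 2-fold apart, with folds from scaled counts or from TPM. Over all tested genes 9.13% were with folds from scaled counts and 9.56% with folds from TPM. Progenitor genes with a mean under 10 counts, such as Gfi1, were not tested. TPM also divides by the effective length of each gene in that library. List members called and at least 2-fold higher in replicate 2 on both scales included Hbb-bt, Bpgm, Prdx2, Pcna, Mcm7, Aurka and Actb, and Hbb-bt shares most of its 31-mers with another gene. For other members the scales differed. Tfrc stood 1.37 times higher in replicate 1 in scaled counts and 2.65 times in TPM, and in replicate 2 Alas2 stood 2.27 times higher in scaled counts and 1.39 times in TPM, and Ermap 2.08 and 1.25 times.

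**Figure D3:**
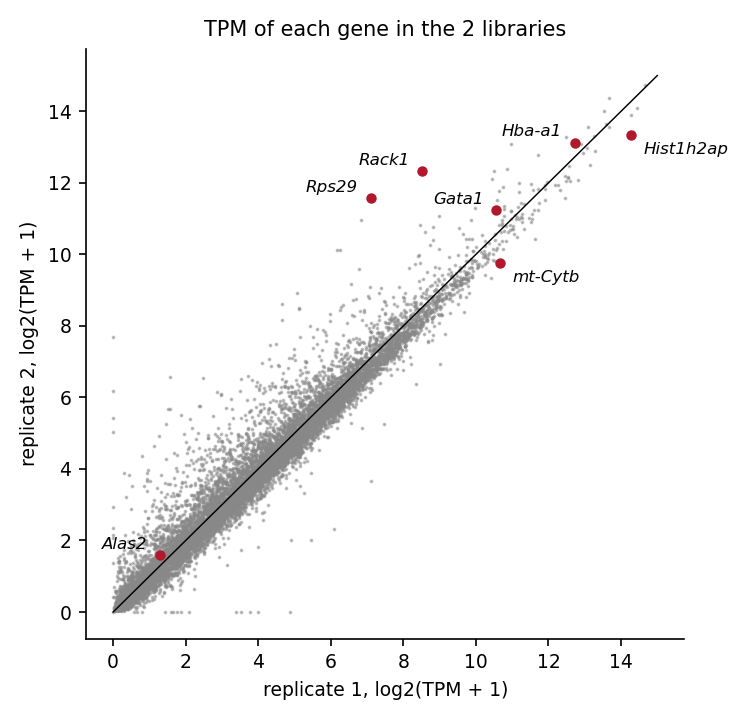
The log2(TPM + 1) of each of the 10863 genes with a mean of at least 10 counts, replicate 1 on the x axis and replicate 2 on the y axis, with the line of equal values and 7 genes named in red. More genes lie far above the line than far below it, among them Rack1 and Rps29, which were picked for the plot after their values were seen.

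Leading transcripts were the same in both libraries for 4416 of 5253 genes with 2 or more transcripts and a mean of at least 5 TPM, or 84.1% (95% Clopper-Pearson interval 83.0 to 85.0%). Gata1 was read from 1 transcript of 1902 nucleotides, which took 99.99% of its TPM in each library. Nfe2, Gfi1b and Runx1 each had a coding transcript at 99.5, 93.1 and 91.9% on average. Klf1 and Epor had 1 transcript each in the tables. The leading coding transcript of Tal1 took 79.1% in replicate 1 and 49.7% in replicate 2, and that of Bcl2l1 took 92.8 and 69.9%. Epb41 was led by a processed transcript at 82.3 ± 1.05% and Slc25a37 by a transcript of the nonsense-mediated decay class at 64.3 ± 4.24% (SD, n = 2). Alas2 was led by a processed transcript at 68.2% in replicate 1 and by a coding transcript at 54.3% in replicate 2, on few counts. The 5 most abundant genes whose leading transcript differed included Rpl18, Ptma, Rpl13a and Ldha. The leading transcript of Rpl13a in replicate 1 took 44.1% there and 0.20% in replicate 2, a spread that limits any statement on isoforms of such genes.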

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

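All alternatives in this part were chosen before the data were examined, except folds from TPM. Of 199 comparisons of main values with an alternative, 182 stayed within the limits set and 17 did not, and the cause was not tested except where named. At a minimum of 5 TPM, which by construction detects fewer genes, 9 red cell membrane, 5 late erythroid maturation, 3 megakaryocyte, 0 mast cell and basophil and 0 T cell genes were detected, and fibroblast genes rose to 1 at 0.5 TPM and to 1 in CPM. The globin share was 0.616% in counts, where length is not divided out. The Pearson correlation was 0.971 with a pseudocount of 0.1, 0.984 with no count filter, 0.965 at a mean of at least 100 counts and 0.977 in protein-coding genes, and the coefficient of variation was 0.288 at a mean of at least 100 counts and 0.274 in protein-coding genes. Genes at least 2-fold apart fell from 992 to 646 at a mean of at least 100 counts, and those higher in replicate 1 from 182 to 44, where fewer genes were tested, and calls fell from 7502 to 2046 with a coefficient of variation of 0.1, which widens the error. Percentiles of gene lists moved more often, in 67 of 124 comparisons. Against random lists of expressed protein-coding genes 23 of 25 were lower, of which 10 with a median under 1 TPM could only be 0. The largest falls were those of red cell membrane genes from 97.9 to 4.495, late erythroid maturation genes from 91.5 to 1.78 and stress genes from 85.6 to 0.425. That choice removes the genes near 0 TPM from the random lists and not from the gene lists. In CPM 16 of 25 moved, 12 of them lower, with endothelial genes going from 10.98 to 22.1, and with TPM rescaled without globin and mitochondrial genes 6 of 24. Without replicate 1 or replicate 2, 9 and 13 of 25 moved, and those of the mast cell and basophil list (36.4) and the T cell list (36.1) lay between 18.99 and 20.8, where the median in each library is 0 TPM. For levels of genes, with 2 libraries, leaving 1 out cannot move a mean by more than the SD, so that check decides nothing for levels. Of 115 named genes, 10 moved by more than the SD with TPM rescaled without globin and mitochondrial genes and 0 with the sum of the transcript table, and FPKM (49) and CPM (90) are other units. No paired analysis was possible because there is only 1 group.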

Other observations

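Tests on GC content between the libraries and of late erythroid genes, folds from TPM, transcript length, reads lost to paralogs and untreated libraries were chosen after the results were seen, as were the gene families and genes named in this part. Cytosolic ribosomal protein genes took 17.7% of TPM in replicate 1 and 20.2% in replicate 2, from 79 detected of 82 genes. Histone genes of the Hist clusters, whose messages mostly lack a poly(A) tail, took 3.36 and 2.13%, with 54 of 64 detected. The ferritin pair Fth1 and Ftl1 held 3.26 and 2.72%, and the metallothionein genes Mt1 and Mt2 held 0.883 and 0.782%. The 13 protein-coding mitochondrial genes took 0.817 and 0.401%, and mt-Cytb stood at 1626 and 860 TPM. Mt1 stood at 1605 TPM in replicate 1 and 3506 TPM in replicate 2, and Mt2 at 7227 and 4316 TPM.

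The labels give the sex of the line as male. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d, which are broadly expressed in male mouse cells, had 0 counts in both libraries, and a count of 0 allows up to 3 counts in each. None of the 183 protein-coding Y-linked genes reached 1 TPM, and all of chromosome Y held 1 and 6.37 counts. Xist also had 0 counts in both libraries, whereas Tsix, the antisense gene that spans it (chromosome X, 103431517 to 103484957), had 5.56 and 4.6 TPM from 1390 and 860 counts, and since strand use is not known the reads of this locus cannot be assigned to either gene with certainty. Hbb-bs was assigned for 99.9% of its TPM to a transcript of 549 nucleotides annotated with a retained intron, not to its coding transcript. Transcripts of that class took 12.6% of TPM in replicate 1 and 13.1% in replicate 2, and led in 11.9 and 11.4% of 5164 protein-coding genes. Top2a stood at 15.1 and 75.3 TPM although its counts were 4012 and 4351.

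Genes of low GC content stood lower. In protein-coding genes log2(TPM + 1) rose by 1.15 per 10 percentage points of GC, which could reflect the biology of these genes or GC content bias of the libraries. Subunits of protein complexes of fixed make-up give a test fixed before its result was seen, since their proteins are made in matched amounts, although their mRNAs need not be. Within 6 complexes with 75 subunits the slope was 2.54 log2 units per 10 percentage points, with a bootstrap 95% interval of 2.03 to 3.05 and a one-sided permutation p of 1e-05, the smallest that 100000 permutations can give. It was 2.38 and 2.72 in the 2 libraries, positive in the proteasome (3.03), eIF3 (2.29), the exosome (3.96), the COP9 signalosome (2.34) and the MCM helicase (1.00), and negative in the CCT chaperonin (-2.77), so bias may lower genes of low GC content here, with no biological explanation tested.

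Far more genes stood over 2-fold higher in replicate 2 than in replicate 1, 840 against 217 on the ratio of scaled counts alone and 856 against 320 on that of TPM, among them Rack1 (367 and 5165 TPM) and Rps29 (136 and 3031 TPM). Reads shared between paralogs are argued against as the whole cause, since 6.67% of the 3615 genes that share no 31-mer were also over 2-fold higher in replicate 2 (Clopper-Pearson 95% interval 5.87 to 7.53%), and the imbalance was 241 against 45 genes there and 198 against 86 in genes sharing at least 50% of 31-mers. After the median ratio of each GC decile was subtracted, the ratio of the counts was 4.68 (3.96 to 5.54), against 3.93 before. Uneven coverage of short transcripts is argued against as the whole cause too, since the ratio was 5.20 (3.201 to 8.86) in the longest of 4 length bins and 3.25 in the shortest. More genes were over 2-fold apart both ways in the shortest bin (348 against 107) than in the longest (104 against 20). In the test first run, the percent over 2-fold higher in replicate 2 fell with length. It was 12.8, 7.62, 6.46 and 3.84% from the shortest bin to the longest, so a part played by length is not excluded. What sets the 2 libraries apart, and which of them departs, stays open, and with 1 group no biological explanation was tested.

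Cells labelled as induced held Gata2 at 963 TPM and 3 genes of later erythroid cells, Alas2, Slc4a1 and Epb42, at least 81.9 times below it. These 3 were picked as low members of their lists after their values were seen and do not stand for the lists, in which Alad had 524, Ank1 117, Sptb 116 and Ermap 98.8 TPM, and the globin genes Hba-a1 and Hbb-bs had 7841 and 7588 TPM. GC content bias is argued against, because among protein-coding genes of its own GC decile Gata2 still ranked 33.7 percentage points above the highest of the 3, Slc4a1, in the closer library. Reads lost to paralogs are argued against as well, since losing every read in a shared 31-mer could lower any of the 3 by at most 1.18 times, although the bound first set, a shared percent under 10 in each gene, was missed by Alas2 at 15.6% and was replaced because the gap is many times larger than such a loss. As a hypothesis for these 3 genes and Gata2 alone, cells that had not been exposed to estradiol or had not yet responded could show this pattern, and it cannot be told apart from an induced state because 0 untreated libraries were analysed here.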
